A study of Drosophila melanogaster with 2 samples.

How the data were processed

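Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on whole Drosophila melanogaster embryos collected 0 to 18 h after egg laying, per the labels. The flies carried a fusion of gooseberry (gsb) with enhanced green fluorescent protein (eGFP), and chromatin was precipitated with an antibody against GFP. Chromatin had been sheared by sonication to 200 to 800 bp, per the labels. The labels give 1 group of 2 biological replicates, each with 1 technical replicate. They point to a possible control experiment, which was not used here. A 2-group comparison was therefore not made, and every enrichment tested here is relative to other regions of the same libraries or of the genome. Whether the deposited peak calls had been set against that control is unknown here.

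The deposited files were peak lists on assembly dm6, per the labels. For each replicate, and for both replicates together, the authors gave a ranked list of candidate regions and a list of the regions that passed a threshold of the irreproducible discovery rate (IDR), a measure of how well the rank of a region is repeated between 2 sets of reads. For both replicates together there was also a conservative thresholded list. The main list here is the combined list, the longer of the 2 joint lists. Each region in the deposited files carries a signal, the peak caller's own value, whose scale is not given in the sources used here. It also carries a score, which the authors' pipeline capped at 1000 and which rises with the significance of the IDR. The lowest score in each deposited thresholded list was 830. All 2877 main-arm peaks of the combined list have a global IDR of at most 0.01. The aligner, the peak caller and their versions are not given in the sources used here. Signal is a value of each peak within its own list, and it was used to describe, rank or filter peaks in that list, to compare ranks between the replicates and to take medians over windows of the genome. The number of reads per library is unknown from peak lists, so no value could be weighted by depth. Intervals of shares below are exact (Clopper-Pearson) binomial intervals at 95% and cover counting error only. Intervals of odds ratios are normal approximations on the log scale, also at 95%.

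Coordinates are those of Release 6 (dm6), written 1-based. Genes and transcription start sites (TSSs) came from Ensembl release 115 on the same assembly, and sequence from the RefSeq copy of Release 6, whose arm lengths were checked against the annotation. Analyses used summits on the 6 main arms (2L, 2R, 3L, 3R, 4 and X). Each summit was put in 1 class in this order of priority: promoter (within 1 kb of a TSS), 5' UTR, coding exon, 3' UTR, intron, other exon, intergenic. Overlap of the replicate lists and the promoter share were tested one-sided against 1000 random placements on the same arms, which allow no p below 0.001. The promoter share was also set against candidate regions that did not pass, with Fisher's exact test.

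There were 18 gene lists and 12 motifs, fixed before the data were examined. Promoter peaks were tested per list with a two-sided Fisher exact test against all other protein-coding genes. Distal peaks, over 1 kb from every TSS, were given to the nearest protein-coding TSS and compared with distal candidate regions that did not pass. Motifs on either strand within 100 bp of the summit were compared with a window of the same width 500 bp away by an exact McNemar test. Motif shares were also compared between the strongest and the weakest of 3 equal groups by signal, and between distal and promoter peaks, with Fisher's exact test. All 6-mers were tested in the same way as the motifs. Peaks per arm were tested with an exact binomial test against the share of candidate regions. Adjusted p-values are Benjamini-Hochberg values over the lists, motifs, 6-mers or arms of each family, and the threshold was 0.05. Peaks of 1 list are not independent replicates, so these tests describe the lists, and values from each replicate's own list are given beside some of them.

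Genes are named by a rule fixed beforehand. It takes the protein-coding gene with the TSS nearest to each of the 20 strongest summits. It takes members of the pax and segment polarity lists, as counts with at most 12 in full. From each other list it takes up to 4 genes with the strongest peak within 1 kb of a TSS, and it adds gsb. Genes with distal peaks outside this rule were chosen after their values were seen.

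The tests of gene lists at promoters, motifs at summits, replicate overlap and promoter share were first tried on simulated data, and the other tests were not. With 30 list genes given 3 times the peak rate among 13945 genes, the list was called in 16 of 20 simulations, and 2 of 340 unchanged lists were called. A motif placed in 1% of 2877 windows was called in 10 of 20 simulations and one placed in 2% in 19 of 20, with 0 of 440 calls for other motifs. Of 1000 simulated peaks with 400 copied to the other list, 402 were found shared. Of 1000 simulated summits with 500 put on a TSS, 620 were found at a promoter.

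The alternatives were the conservative list, the stronger peaks by signal, each replicate's own list, other overlap rules, promoter windows of 500 bp and 2 kb, protein-coding genes only, other backgrounds for lists and arms, motif windows of 50 and 200 bp, dinucleotide-shuffled sequence and candidate regions matched on GC content. For the gene lists, 10000 random lists matched on TSS number and gene territory were drawn, and the value is the ratio of the list's count to their mean count, with 0.5 added to both. A global IDR of at most 0.001, 1 summit per 300 bp, genes counted in place of distal peaks, the same without gsb and gsb-n, and a stratification by GC content were added after seeing the data. Computation used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.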

Results

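Binding of gooseberry (gsb), a Pax transcription factor with a paired domain and a homeodomain that acts in segment polarity and the nervous system of the embryo, was mapped in whole embryos of 0 to 18 h by ChIP-seq of a gsb-eGFP fusion protein. The data are 2 biological replicates of 1 group. The question the design poses is where in the genome the tagged protein was enriched and how well the replicates match. The authors' combined list held 2888 peaks, of which 2877 lay on the main chromosome arms. The replicate 1 list held 1877 peaks and the replicate 2 list 1704, a ratio of 1.10. The conservative list held 2721, and the combined list was 1.06 times as long. The combined peaks were chosen from 141664 candidate regions. Their median width was 364 bp, which is also the width of 84.4% of them, so widths carry little information. The number of reads behind the lists is unknown.

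Peaks were largely shared between the replicates. Of 1864 replicate 1 summits on the main arms, 1241 lay in a replicate 2 peak (66.6%, 95% interval 64.4 to 68.7), against 0.393% at random (permutation p = 0.001, one-sided, the smallest that 1000 placements allow). In the other direction, 1242 of 1701 replicate 2 summits were shared (73.02%, 95% interval 70.8 to 75.1). Of the 500 strongest replicate 1 summits, 488 were shared. Across the 1241 shared peaks, signal in the 2 replicates had a Spearman rho of 0.818 (95% bootstrap interval 0.792 to 0.842), a correlation across peaks, which are not independent replicates. These peaks were selected for passing in both replicates, and over all 72019 matched candidate regions rho was 0.368. Of the 2877 combined peaks, 1226 had a summit in a passing peak of both replicates, 458 in that of replicate 1 only, 327 in that of replicate 2 only and 866 in that of neither, although 93.8% lay in a candidate region of both. That is weak support, since 72019 of all 123585 replicate 1 candidate regions on the main arms had their summit in a replicate 2 candidate region.

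**Figure D1:**
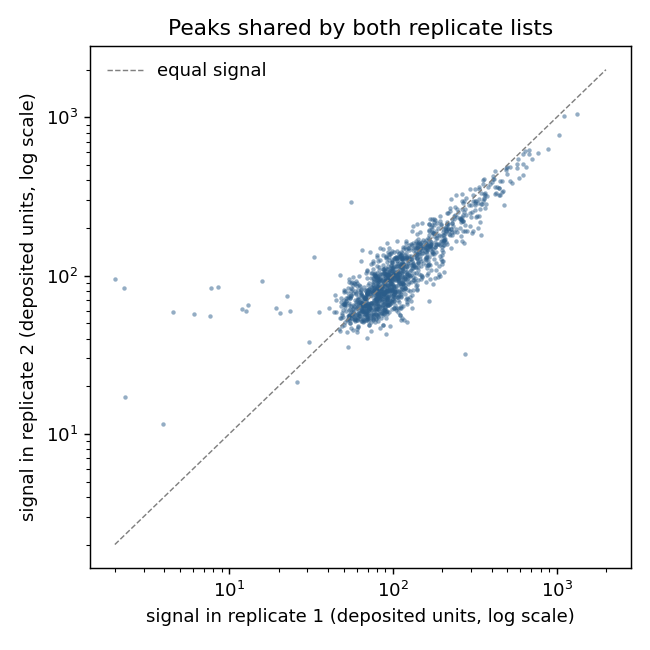
Signal of the 1241 peaks shared by both replicate lists, replicate 1 on the horizontal and replicate 2 on the vertical axis, both in the deposited units on log scales. Each point is a peak and the dashed line marks equal signal; the Spearman rho is 0.818.

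At the gsb gene itself (2R, 25061964 to 25064643, plus strand), 2 peaks of the combined list were present, and both were of modest signal. The promoter peak (25061692 to 25062055) had its summit 90 bp from the TSS and a signal of 87.6, below the median of 112 for all combined peaks. The signal of the region was 35.8 in replicate 1 and 51.2 in replicate 2, and neither replicate's own list held it. A peak in the coding exon (25063391 to 25063754) had a signal of 100 (34.0 in replicate 1 and 74.7 in replicate 2) and was in neither replicate's list. The neighbouring paralogue gsb-n had a peak in an intron (25045219 to 25045582) with a signal of 89.9, and this one passed in replicate 1 only. Candidate regions within 50 kb of gsb that did not pass had a median signal of 36.4, against 23.8 for all windows of 100 kb (99.9 percentile).

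**Figure D2:**
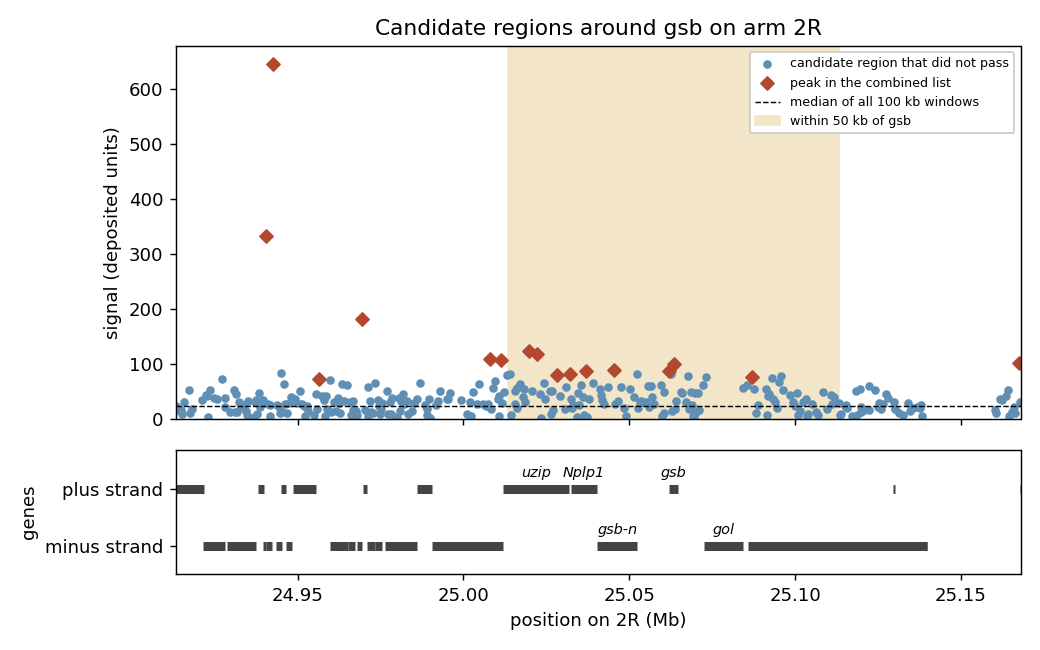
Signal in the deposited units (vertical axis) of candidate regions against position on 2R in Mb (horizontal axis), with the genes of each strand beneath and the 50 kb on either side of gsb shaded. The 9 peaks in the shaded window have signals of 75.9 to 124, and the dashed line is the median of 100 kb windows, 23.8.

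Promoters held most of the peaks. Of the 2877 summits, 1708 lay within 1 kb of a TSS (59.4%, 95% interval 57.5 to 61.2), against 23.5% at random (permutation p = 0.001, one-sided). Among candidate regions that did not pass, the share was 26.8% (Fisher exact odds ratio 3.99, p = 2.75e-286). Introns held 27.0% of the summits, intergenic sequence 8.34% and coding exons 3.48%, while coding exons held 17.8% of the candidate regions that did not pass. Within 200 bp of a TSS lay 32.3% of the peaks and 6.80% of those candidate regions. The promoter share was 69.1% in the strongest and 50.99% in the weakest of 3 equal groups by signal, of 959 peaks each (Fisher exact p = 5.86e-16). It was 62.4% in the replicate 1 list and 65.1% in the replicate 2 list. The share of coding exons was lower in these lists than in the combined list, at 0.697% in replicate 1 and 1.47% in replicate 2.

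**Figure D3:**
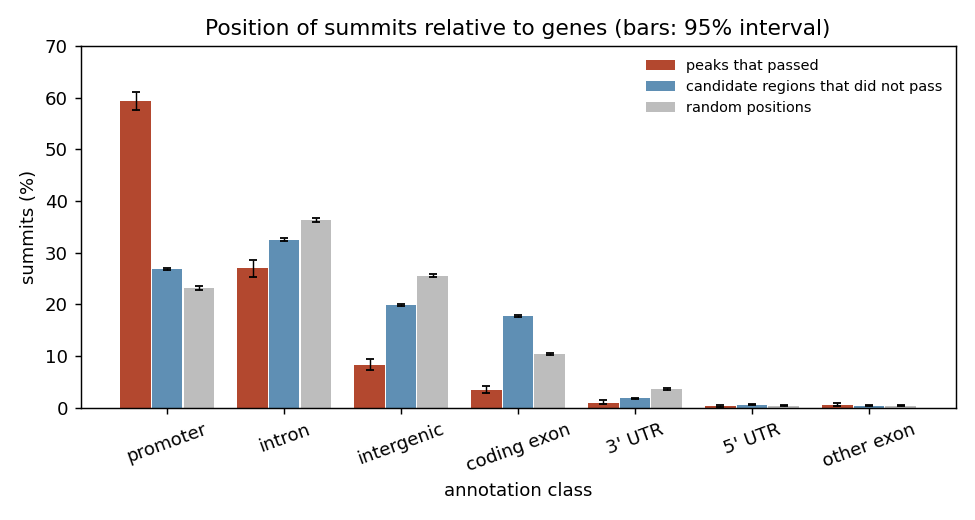
Share of summits (%) in each annotation class for the 2877 combined peaks, the 136363 candidate regions that did not pass and random positions on the same arms. Bars start at 0 and error bars are exact 95% intervals; promoters hold 59.4% of the peaks and 26.8% of the candidate regions.

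The strongest peaks lay mostly at promoters, among them those of Ugalt, CG14100 and mRpL41. Of the 20 strongest, 17 were at promoters, 14 within 200 bp of a TSS, and all 20 were in the lists of both replicates. The highest signal, 2400.8 (1337 in replicate 1 and 1048 in replicate 2), was in an intron of CG11050 (2L, 6612450 to 6612926), 1021 bp from its TSS. The next was 38 bp from the TSS of Ugalt, a UDP-galactose transporter gene (X, 2703716 to 2704054), with a signal of 2108 (1110 and 1015). CG14100 followed with 1818. The mitochondrial ribosomal protein genes mRpL41 (1509) and mRpL23 (996) were in this group, as were ph-p (1347), a Polycomb group gene, and Trl (1141), which encodes GAGA factor and had its peak in an intron 1530 bp from the TSS. Others were CenG1A (1314), CG7601 (1257), Tcs5 (1254), PNPase (1253), Art3 (1211), CG5611 (1146), the translation factor gene eIF6 (1114), CG18549 (1077), CG32772 (1061), the transcription factor gene Adf1 (1004), Fkbp14 (983) and CG13390 (973). The peak nearest to CG4004 (1051) was 5084 bp from that gene's TSS and 466 bp from another annotated TSS.

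Among gene lists, ribosomal protein genes and highly transcribed housekeeping genes had promoter peaks more often than other genes. Among all, 1931 of 13945 protein-coding genes (13.8%) had a summit within 1 kb of a TSS. Of 89 ribosomal protein genes, 49 did (55.1%, 95% interval 44.1 to 65.6; Fisher exact odds ratio 7.79, adjusted p = 1.00e-18). The odds ratio was 7.29 in the replicate 1 list and 8.41 in the replicate 2 list. RpS27 (signal 409), RpL34b (353), RpL32 (342) and RpL7 (277) had the strongest peaks. Of 20 housekeeping genes, 11 had a peak (55.0%, 95% interval 31.5 to 76.9; Fisher exact odds ratio 7.64, adjusted p = 0.000158), among them the glycolytic genes Gapdh2 (763) and Eno (492), the actin gene Act5C (244) and the chaperone gene Hsp83 (227). Against random lists matched on TSS number and gene territory, the adjusted p was 0.0036 for ribosomal protein genes and 0.0504 for housekeeping genes.

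Lists of developmental regulators did not pass the test at promoters. In the segment polarity list, 4 of 31 genes had a promoter peak (12.9%, Fisher exact odds ratio 0.922, adjusted p = 1). These were sgg (signal 287), a kinase of Wnt signalling, nkd (177), a feedback inhibitor of the same pathway, the ligand gene Wnt6 (111) and gsb. The classic segment polarity genes wg, en and hh had no passing peak within 1 kb of a TSS, and their highest candidate regions there had signals of 51.5, 38.4 and 45.6. In the pax list, 2 of 10 genes had one, gsb and Poxm (158), for an odds ratio of 1.56 by Fisher's exact test (adjusted p = 0.972). None of 10 Hox genes and cofactors did (95% interval up to 30.8%; Fisher exact adjusted p = 0.752). Counts were 2 of 23 for gap and pair-rule genes (cnc, 101, and cad, 95.4), 5 of 35 for neuroblast and neuron genes (elav, 575, brat, 445, numb, 253, and dpn, 78.7, were the strongest) and 2 of 12 for glia (moody, 662, and sim, 92.3). They were 6 of 30 for mesoderm and muscle (tin, 291, sls, 248, Poxm and mbc, 89.6), 1 of 17 for epidermis and cuticle (crb, 157), 2 of 14 for gut and endoderm (fkh, 158, and cad) and 3 of 19 for the Notch pathway (numb, E(spl)m3-HLH, 137, and mam, 98.0). The Dpp pathway had 2 of 16 (Mad, 120, and brk, 85.7). Adjusted p-values of these lists ranged from 0.752 to 1. The pax genes ey, toy and sv had no candidate region within 1 kb of a TSS, so no peak could pass there. All of them lie on chromosome 4, where candidate regions were scarce. Some segment polarity genes, on chromosome 4 and elsewhere, and some Hox genes also had no candidate region within 1 kb of a TSS.

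The EGFR and FGF pathway list had 6 of 16 genes with a promoter peak (37.5%, Fisher exact odds ratio 3.74, adjusted p = 0.0583), among them the ligand gene spi (302), aos (143), aop (120) and bnl (115). With the conservative list the same test passed (odds ratio 5.12, exact adjusted p = 0.0162), as it did within 500 bp (4.84, exact adjusted p = 0.0244). It did not pass in the replicate 1 list (exact adjusted p = 0.238) or the replicate 2 list (exact adjusted p = 0.564). Nor did it among the stronger peaks by signal (exact adjusted p = 0.195) or at a global IDR of at most 0.001 (exact adjusted p = 0.11). The ratio to the mean count of the matched random lists was 1.96 (permutation adjusted p = 0.348). Odorant receptors and gustatory receptors, which act in sensory neurons, each had 2 of 60 genes (3.33%, Fisher exact odds ratio 0.214, adjusted p = 0.0583). The odorant receptor genes were Or88a (209) and Or69a (69.4), and the gustatory receptor genes Gr64a (103) and Gr32a (102). Of 17 chorion and vitelline genes none had a peak (Fisher exact adjusted p = 0.462), and of 22 testis genes 1 did, bgcn (227, adjusted p = 0.752). With a window of 500 bp, 5 lists passed (3 more and 2 less often bound), and with 2 kb, 4 lists (3 and 1).

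**Figure D4:**
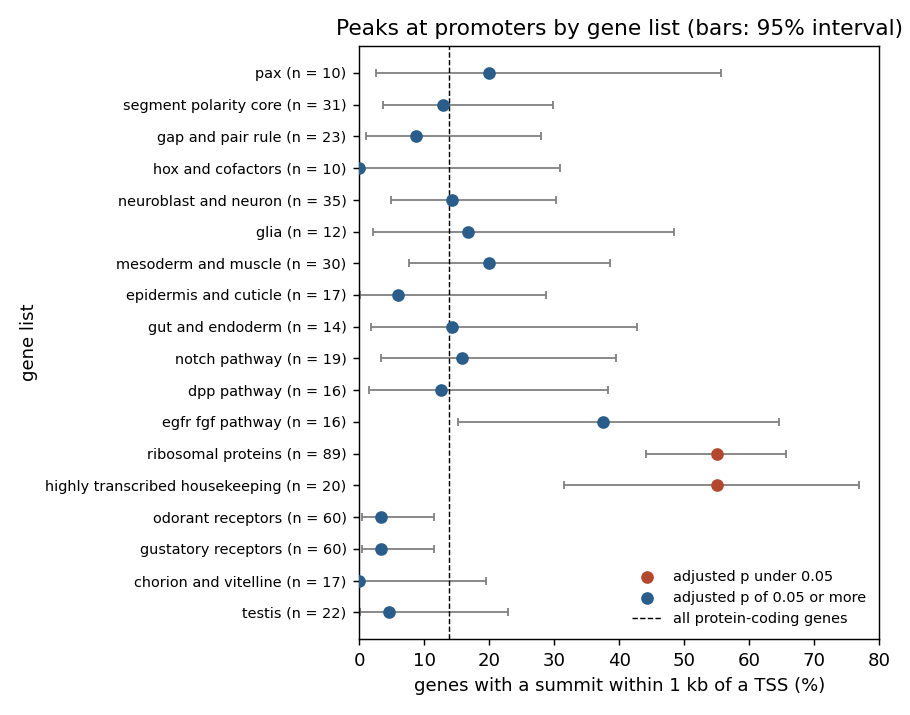
Share of each list's genes (%) with a summit within 1 kb of a TSS, with exact 95% intervals and the number of genes per list. The dashed line is the 13.8% of all protein-coding genes; ribosomal protein and housekeeping genes lie at 55.1% and 55.0%.

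Distal peaks lay near genes of the Dpp pathway, the EGFR and FGF pathways and the mesoderm list more often than distal candidate regions that did not pass. Of 1169 distal peaks, 12 were nearest to Dpp pathway genes (Fisher exact odds ratio 3.90, adjusted p = 0.00202), 7 of them at shn and 2 each at sog and Dad. Mesoderm and muscle genes had 17 (Fisher exact odds ratio 2.81, adjusted p = 0.00211), including 7 at Mef2, a muscle transcription factor gene, and 4 at kirre. EGFR and FGF pathway genes had 15 (Fisher exact odds ratio 2.35, adjusted p = 0.0187), spread over aop, sty, S, pnt, ths, aos and bnl. Gap and pair-rule genes had 14 (Fisher exact odds ratio 2.11, adjusted p = 0.0364), of which 6 were near hairy (hry). The gap and pair-rule call was lost in every alternative, with an odds ratio of 0.549 in the replicate 2 list, and the mesoderm call was lost in each replicate's own list (exact adjusted p = 0.0793 and 0.0912), in the conservative list (0.159), among the stronger peaks by signal (0.0978) and at a global IDR of at most 0.001 (0.539). The Dpp call was also lost among the stronger peaks by signal (exact adjusted p = 0.0978). None was nearest to an odorant receptor gene, against 582 of 99801 candidate regions (Fisher exact adjusted p = 0.0157), a call lost in each replicate's own list, among the stronger peaks by signal and at a global IDR of at most 0.001.

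Neighbouring peaks at 1 gene are not independent, and genes with a distal peak were therefore counted as well. This count takes no account of how many candidate regions a gene holds, which favours genes with many of them: the segment polarity genes were nearest to 700 of the 99801. Of 16 EGFR and FGF genes, 7 had a distal peak (43.8%, Fisher exact odds ratio 9.02, adjusted p = 0.0022). By this count segment polarity genes (8 of 28, Fisher exact adjusted p = 0.0106) and Hox genes with cofactors (4 of 9, adjusted p = 0.0221) passed as well, and the Dpp, mesoderm, gap and odorant receptor lists did not (adjusted p = 0.0692 each). The segment polarity genes were ptc, the Hedgehog receptor gene, with 2 peaks up to 173 in signal, fz2, slp2 (191), nkd, mid, Notum, gsb and gsb-n. With gsb and gsb-n left out, 6 of 26 segment polarity genes remained and the call was lost (Fisher exact adjusted p = 0.0657), while the Hox call was kept (0.0329). By peaks, the segment polarity list did not pass (10 peaks, Fisher exact adjusted p = 0.745), nor did the Hox list (6, adjusted p = 0.745) or the pax list (2, adjusted p = 0.745). The remaining lists gave adjusted p-values from 0.14 to 1: neuroblast and neuron 4 peaks, glia 5, epidermis and cuticle 4, gut and endoderm 4, Notch 2, ribosomal proteins 1, housekeeping 2, gustatory receptors 1, and chorion and testis 0.

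Binding sites known for the paired domain and the homeodomain did not pass the test at the summits. The core GTCACGC was within 100 bp of 0.869% of summits (95% interval 0.563 to 1.28) and of 0.695% of windows 500 bp away (exact McNemar adjusted p = 0.551). The homeodomain monomer TAATTA was in 13.5% and 11.7% (ratio 1.15, exact adjusted p = 0.128), and dimers with 2 or 3 bases between the sites were in 1.91% against 1.25% and 2.22% against 1.43% (adjusted p = 0.128 and 0.119). The monomer passed in each replicate's own list, with ratios of 1.29 in replicate 1 and 1.45 in replicate 2. Against dinucleotide-shuffled sequence it passed in the opposite direction (ratio 0.845, exact adjusted p = 0.0124), and against candidate regions matched on GC content its ratio was 0.882 (exact adjusted p = 0.133).

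The element bound by the promoter factor DREF, TATCGATA, was in 2.57% of summits and 0.799% of control windows (ratio 3.17, exact McNemar adjusted p = 1.76e-06). Its ratio was 3.296 in the replicate 1 list, 6.06 in the replicate 2 list and 2.71 against GC-matched candidate regions. The site of M1BP, another factor of housekeeping promoters, was in 0.973% and 0.382% (exact adjusted p = 0.0569), and it passed against GC-matched candidate regions (ratio 4.38, adjusted p = 0.000749). The GAGA repeat (ratio 1.91, exact adjusted p = 8.36e-05) and the E-box (ratio 1.27, exact adjusted p = 0.0111) also passed against GC-matched candidate regions. Neither control was matched on distance to a TSS, and promoters held 59.4% of the summits and 26.8% of candidate regions that did not pass. These calls therefore cannot separate motifs of the peaks from motifs common at promoters. Against the windows 500 bp away the remaining motifs did not pass (adjusted p from 0.128 to 0.388): GAGA repeat 4.28% of summits (4.83% of control windows, the opposite direction), Zelda 1.18%, E-box 10.8%, grainy head 0.243%, pangolin 2.61% and POU 2.82%.

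**Figure D5:**
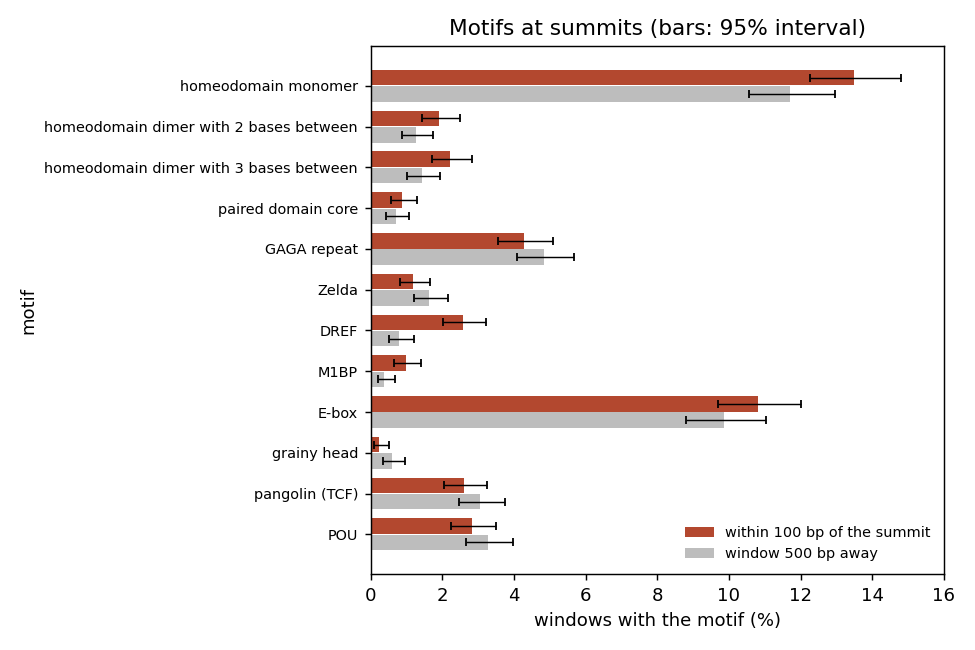
Share of windows (%) with each motif within 100 bp of the 2877 summits and in windows 500 bp away, with exact 95% intervals. The DREF element is at 2.57% against 0.799%, and the paired domain core at 0.869% against 0.695%.

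Among all 6-mers, 259 of 2080 were more frequent at summits than in control windows and 279 less frequent. By ratio, ACAGTG led, in 19.9% of summits and 8.34% of control windows (ratio 2.38, exact McNemar adjusted p = 5.47e-34). It was followed by AGGGTA (2.21), ACTGTA (2.08), ACACTG (2.08), ACCCTA (2.05), ATACCC (1.99), ACTGTG (1.94), AGTGTA (1.94), CGATAG (1.90) and ACTAGT (1.90). All 10 were also more frequent than in GC-matched candidate regions, where ACAGTG had a ratio of 2.43, and of the 259 only 83 were. These controls were not matched on distance to a TSS either.

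Motif content differed between classes of peaks. The strongest peaks held the homeodomain monomer more often than the weakest (17.4% against 10.01% of 959 peaks each, Fisher exact adjusted p = 3.61e-05), as they did the dimer with 2 bases between (2.92% against 0.834%, adjusted p = 0.0043), and the E-box less often (8.34% against 13.2%, adjusted p = 0.00409). The strongest group had a mean GC content of 35.5% and the weakest 45.0%, and none of the 12 motifs passed once the comparison was stratified by GC content. Without that stratification, only the homeodomain monomer passed in each replicate's own list, with ratios of 1.55 in replicate 1 and 1.49 in replicate 2. Promoter peaks held the DREF element in 4.10% and distal peaks in 0.342% (Fisher exact adjusted p = 4.29e-11), and the M1BP, GAGA and E-box motifs were also less frequent in distal peaks (adjusted p = 0.000782, 0.0104 and 0.0305). Zelda sites, bound by a factor of early zygotic genes, were more frequent in distal peaks (1.80% against 0.761%, Fisher exact adjusted p = 0.0329). In the replicate 1 list the Zelda and M1BP calls were lost (exact adjusted p = 0.0877 and 0.0909), and in the replicate 2 list the GAGA and E-box calls (0.349 and 0.0678). The paired domain core did not differ by the test (0.513% distal, 1.11% promoter, Fisher exact adjusted p = 0.207), nor did the homeodomain monomer (13.8% and 13.3%, adjusted p = 0.739).

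By chromosome arm, 3L held 648 peaks, 1.13 times its share of candidate regions (exact binomial adjusted p = 0.0015), and 3R held 639, 0.867 times its share (adjusted p = 0.000153). The 3L call was lost in the replicate 2 list (ratio 1.06, exact adjusted p = 0.361) and among the stronger peaks by signal (1.10, exact adjusted p = 0.103) and at a global IDR of at most 0.001 (1.07, exact adjusted p = 0.369). Arms 2L (517 peaks), 2R (577), X (493) and 4 (3) did not pass, with adjusted p-values from 0.131 to 0.54. Set against arm length, neither 3L nor 3R passed (exact binomial adjusted p = 0.0928 and 0.0822), and chromosome 4 had fewer peaks than its length gives (ratio 0.104, adjusted p = 1.15e-08). Candidate regions were themselves scarce on chromosome 4, which held 0.0601% of them. Against that share its ratio was 1.73 (exact binomial adjusted p = 0.301), so the low count by length does not show that the protein avoids this arm.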

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

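Both results here lie outside the main measurement, and neither was looked for beforehand. On unlocalised scaffolds of the X chromosome, 11 combined peaks passed among 479 candidate regions (2.30%), close to the 2.07% of candidate regions that passed on the main arms. The count varied between lists: off the main arms the replicate 1 list held 13 peaks, the replicate 2 list 3 and the conservative list 6. On the Y chromosome 0 of 425 candidate regions passed, which allows a share of up to 0.706%, and on unplaced scaffolds 0 of 1208, which allows up to 0.248%. No control library was used here, so these peaks stand out only against the limit that a count of 0 allows.

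In the ranked list, 87 regions reached the score of the combined list and were absent from it, 81 of them on the main arms. The strongest (2L, 480918 to 481250) had a signal of 1912, which would have ranked it 3 in the combined list, and 47 of the 87 were above the median signal of the combined peaks. Which step left them out is not given in the sources used here.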

How the results depend on the processing

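A global IDR of at most 0.001, 1 summit per 300 bp, genes counted in place of distal peaks (also without gsb and gsb-n) and the stratification by GC content were chosen only after results were seen. Among main values and counts of calls, 33 kept their side and size under an alternative and 36 did not. Among single lists, motifs and arms, 477 kept direction and side of the threshold, 51 lost their call, 29 gained one, 2 moved and 104 turned direction, most of these from 1 uncalled value to another. The cause was not tested for any change. Values below that turned lie on the other side of 1 from those of the combined list. A global IDR of at most 0.01, the authors' own limit, removed no peak (2877 of 2877 remained) and gave no values. No paired analysis was possible because there was 1 group. The number of reads per library is unknown, so what depth limits could not be measured. Ribosomal protein promoters and the DREF element passed under every alternative, and the EGFR and FGF list passed under every alternative for distal peaks. No motif control was matched on distance to a TSS.

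With all candidate regions, the rank correlation of signal was 0.368. With a global IDR of at most 0.001, counts were 1195 peaks, 2 lists passing for distal peaks, 2 motifs passing at summits, 0 motifs passing by signal, 2 motifs passing between distal and promoter peaks, 1 arm passing. Promoter odds ratios turned to 0.989 (gut). Distal odds ratios turned to 0 (pax), 0.732 (segment polarity), 0.449 (gap and pair-rule), 0.583 (Hox), 0 (epidermis), 2.34 (Notch), 1.15 (gustatory receptors). Summit ratios turned to 0.838 (E-box), 1.05 (pangolin), 1.06 (POU). Strongest-to-weakest ratios turned to 0.8004 (GAGA repeat), 0.751 (DREF), 0.883 (pangolin). Distal-to-promoter ratios turned to 1.14 (dimer with 2 bases). Arm ratios turned to 0.952 (2R), 1.13 (X). With the conservative list, counts were 3 lists passing for distal peaks. The promoter odds ratios turned to 1.26 (segment polarity), 1.51 (Dpp). The distal odds ratios turned to 0.882 (segment polarity), 0.520 (gut), 1.34 (Notch). The summit ratios turned to 1.09 (GAGA repeat), 1.12 (Zelda). With the stronger peaks by signal, counts were 1 list passing for distal peaks, 2 motifs passing at summits, 0 motifs passing by signal, 3 motifs passing between distal and promoter peaks, 1 arm passing. Promoter odds ratios turned to 0.993 (neuroblast), 0.963 (glia), 0.815 (gut). Distal odds ratios turned to 0 (pax), 0.579 (segment polarity), 0.462 (Hox), 1.85 (Notch). Summit ratios turned to 0.878 (E-box), 1.05 (POU). The strongest-to-weakest ratios turned to 0.867 (dimer with 3 bases), 0.760 (GAGA repeat), 0.715 (DREF). The distal-to-promoter ratios turned to 1.05 (dimer with 2 bases). The arm ratios turned to 0.943 (2R), 1.12 (X). With 500 bp from a TSS, counts were 5 lists passing at promoters. The promoter odds ratios turned to 1.19 (segment polarity). With 2 kb from a TSS, counts were 4 lists passing at promoters. Promoter odds ratios turned to 0.938 (neuroblast), 2.06 (Dpp). With only genes with a candidate region, promoter odds ratios turned to 0.980 (neuroblast), 0.998 (gut). With matched random lists, counts were 1 list passing at promoters. Ratios of the list count to the matched mean count turned to 0.886 (neuroblast), 0.821 (glia), 0.993 (mesoderm), 0.933 (gut). With the nearest TSS within 20 kb, distal odds ratios turned to 0.917 (segment polarity), 0.744 (Hox). With genes counted in place of peaks, counts were 3 lists passing for distal peaks. The distal odds ratios turned to 1.15 (neuroblast), 1.77 (Notch). With genes counted and gsb and gsb-n left out, counts were 2 lists passing for distal peaks. Distal odds ratios turned to 0 (pax), 1.15 (neuroblast), 1.78 (Notch). With 1 summit per 300 bp, counts were 2 motifs passing at summits. The summit ratios turned to 0.925 (paired domain core). With 50 bp either side, counts were 3 motifs passing at summits. Summit ratios turned to 0.972 (E-box), 1.19 (POU). With 200 bp either side, counts were 4 motifs passing at summits. The summit ratios turned to 1.27 (GAGA repeat). With dinucleotide-shuffled sequence, counts were 8 motifs passing at summits. Summit ratios turned to 0.845 (homeodomain monomer), 0.600 (paired domain core), 3.48 (GAGA repeat), 1.07 (POU). With GC-matched candidate regions, counts were 4 motifs passing at summits, 150 6-mers more frequent. The summit ratios turned to 0.882 (homeodomain monomer), 1.91 (GAGA repeat), 1.13 (Zelda), 1.36 (grainy head). With stratification by GC content, counts were 0 motifs passing by signal. Strongest-to-weakest common odds ratios turned to 0.948 (homeodomain monomer), 0.982 (dimer with 3 bases), 1.09 (paired domain core), 0.932 (POU). With arm length as the base, counts were 1 arm passing. Arm ratios turned to 0.104 (chromosome 4).

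With each replicate's own list in place of the combined list, the lowest and highest values were 1701 to 1864 peaks, 2 to 3 lists passing for distal peaks, 3 to 4 motifs passing at summits, 1 motif passing in each by signal, 3 motifs passing in each between distal and promoter peaks. Promoter odds ratios were 0 to 1.01 (pax), 0.976 to 1.03 (segment polarity), 0.854 to 0.897 (neuroblast), 0.870 to 1.82 (glia), 0.683 to 1.01 (mesoderm), 0.569 to 1.28 (epidermis), 0 to 0.701 (gut), 0.607 to 1.37 (Dpp). Distal odds ratios were 0.682 to 1.88 (segment polarity), 0.549 to 2.13 (gap and pair-rule), 0.715 to 1.54 (Hox), 0 to 0.901 (gut), 1.30 to 1.32 (Notch), 0 to 1.09 (epidermis). Summit ratios were 0.920 to 1.23 (paired domain core), 0.873 to 0.964 (E-box), 1 to 1.21 (pangolin). Strongest-to-weakest ratios were 0.668 to 1 (DREF), 0.753 to 1.49 (paired domain core), 0.676 to 1.04 (GAGA repeat), 0.858 to 1.49 (M1BP). Arm ratios were 0.926 to 0.972 (2R), 0.822 to 1.36 (chromosome 4), 1.09 to 1.14 (X), 0.994 to 1.04 (2L).

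Of the values that turned, these passed in the alternative: the GAGA repeat with 200 bp either side (exact adjusted p = 0.00422), with shuffled sequence (2.52e-13) and with GC-matched candidate regions (8.36e-05), the homeodomain monomer with shuffled sequence (exact adjusted p = 0.0124), X without replicate 1 (exact adjusted p = 0.0228) and chromosome 4 by arm length (exact adjusted p = 1.15e-08). Those called before and not after were the homeodomain monomer by signal and the gap and pair-rule list for distal peaks.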

Other observations

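The test of tRNA genes and the stratification by GC content had their outcomes written down before they were run. The other tests in this part were chosen after the result was seen. Genes that share a divergent promoter were counted as having a promoter peak more often than others. Of 4568 protein-coding genes whose 5' end lay within 1 kb of the 5' end of a gene on the opposite strand, 950 had a promoter peak (20.8%), against 981 of 9377 others (10.5%, Fisher exact odds ratio 2.25, p = 1.18e-58). A peak within 1 kb of both TSSs counts for both genes, which by itself raises this share. The values therefore do not show that divergent promoters are bound more often, and this p overstates the evidence. Of the 89 ribosomal protein genes, 54 had a divergent promoter, against 4568 of all 13945 protein-coding genes. The random lists were not matched on this, and how far it raises the ribosomal protein count was not tested. Among noncoding genes, a summit lay within 1 kb of the TSS of 6 of 32 snRNA genes (18.8%, 95% interval 7.21 to 36.4), 36 of 269 snoRNA genes (13.4%), 223 of 3261 other ncRNA genes (6.84%) and 10 of 290 tRNA genes (3.45%).

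Some peaks are shoulders of stronger ones. In the combined list 109 peaks had a signal below 23.6, the median of the candidate regions that did not pass, and all 109 lay 199 to 275 bp from a stronger passing summit. In the replicate lists, 63 peaks of replicate 1 and 45 of replicate 2 were below the medians of their own candidate regions (14.2 and 14.1), and all of them lay 199 to 222 bp and 199 to 242 bp from a stronger passing summit. Keeping 1 summit per 300 bp left 2729 peaks.

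Around gsb, 9 combined peaks lay within 50 kb, with signals of 75.9 to 124, more than in 98.4% of 1214 windows of 100 kb, while the replicate 1 list held 2 there (59.8 percentile) and the replicate 2 list 7 (99.1 percentile). The 9 lay in introns, at promoters and, at gsb, Nplp1 and gol, in coding exons. Coding exons held 3.48% of all combined peaks and 17.8% of candidate regions that did not pass. The 115 candidate regions within 50 kb of gsb that did not pass had a median signal of 36.4, against 23.8 for all windows, which put it at the 99.9 percentile (99.8 in replicate 1 and 99.7 in replicate 2). A candidate explanation is that a tagged transgene carries extra copies of the region and raises its background. At 75 to 150 kb the median was at the 93.5 percentile to the left (113 regions), while the right held 11 regions, fewer than the 20 required of a window, and windows at genes without the tag were at 28.9 (en), 46.2 (wg), 76.3 (prd), 90.3 (hh) and 96.8 (eve), with up to 99.4 in replicate 1 (eve) and 98.0 in replicate 2 (prd). Binding of the protein at its own locus stays open: the strongest of the 9 peaks was at the 56.2 percentile of all peaks, which neither requires nor excludes it, and copy number was not measured here.

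Of the ribosomal protein genes 55.1% had a promoter peak, against 13.6% of other genes, and no control library was used here. Their number of TSSs and gene territory were not the whole cause, since the adjusted p against random lists matched on both was 0.0036. An enrichment at highly transcribed genes of every kind, whatever protein is precipitated, would raise tRNA genes too. Among all noncoding genes they had peaks less often than the others (odds ratio 0.458, 95% interval 0.241 to 0.871, Fisher exact p = 0.0115), and among those over 2 kb from coding TSSs 2 of 167 had one (odds ratio 0.276, exact p = 0.0611). The narrower form, an enrichment at genes highly transcribed by RNA polymerase II, could not be decided by the test made. Highly transcribed housekeeping genes had a promoter peak in 55.0% of cases, which goes with this form. Against matched random lists their permutation adjusted p was 0.0504. Counted as 1 group, snRNA and snoRNA genes over 2 kb from coding TSSs had peaks in 9 of 111 cases. Other ncRNA genes as far away had them in 76 of 1812 (odds ratio 2.02, 95% interval 0.982 to 4.14, exact p = 0.0581). The share was 20% for snRNA genes (4 of 20, 95% interval 5.73 to 43.7). It was 5.49% for snoRNA genes (5 of 91, 95% interval 1.81 to 12.4) and 4.19% for the other ncRNA genes. The snRNA and snoRNA genes were not tested apart, and a biological explanation was not tested.

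The strongest peaks held the homeodomain monomer more often than the weakest, with shares of 17.4% and 10.01%. Within bins of GC content the common odds ratio was 0.948 (95% interval 0.703 to 1.28), so base composition may account for the difference. The stratified intervals were wide for the rarer dimers (1.69, 95% interval 0.739 to 3.88, with 2 bases between), for which the question stays open. No biological explanation was tested.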
